A study of Homo sapiens with 6 samples.

How the data were processed

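Total RNA from PC-9, HCC827 and H322 cells was extracted with Trizol, and biotin-labelled cRNA was hybridised to Affymetrix Clarion S arrays, per the labels' protocols. The deposited values are probe set intensities on a linear scale, with medians between 148 and 157 and a range from 3.64 to 295568 on the 6 arrays. They were made by the authors with Affymetrix Expression Console, per the submitters' processing notes. Its version, the background correction, the summarisation method and the scaling between arrays are not given in the sources used here, and no genome build is named, so no coordinates are printed. The near-equal medians show that the arrays had been brought to a like scale, and such scaling would hide a change shared by most genes.

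From these intensities log2(value + 1) was computed for each of the 24351 probe sets. The design written before the data were examined allowed for log2 values, and since the values turned out to be linear, its alternative offset of 16 was run too. A log2 change with an offset understates the change of dim genes. Gene symbols came from the platform annotation: 17709 probe sets had 1 gene symbol, 0 had several and 6642 had none. All 17709 were found by gene identifier in a RefSeq gene table, which changed 0 symbols. Where several probe sets shared a symbol (20 genes), the one with the highest mean over all arrays was kept, which left 17687 genes. The 612 negative control probe sets of the array gave the background. Their 95th percentile lay between 6.92 and 7.47 on the log2 scale, and 48.8% to 52.4% of the genes on each array lay above it. A gene below it on one array of a pair has only a bound, given as "at least" with the dim array set to that percentile, and where both arrays lay below it no fold is given. No detection call of the array software was used. Folds between control arrays follow the same rule. Counts of genes at a fold threshold use the log2 differences without these bounds.

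Samples were grouped by the genotype, cell line and treatment in the labels. Erlotinib was compared with control by limma (version 3.58.1 in R 4.3.3, with statmod 1.5.0 and matrixStats 1.5.0) on the 4 arrays of PC-9 and HCC827, with lmFit and eBayes with a trend of the spread on the level, cell line as a block, a two-sided test and Benjamini-Hochberg adjustment over all genes at 0.05. The lines are the replicates and the pairing comes from the cell line: control and treated arrays of a line correlated across genes at 0.991 for PC-9 and 0.988 for HCC827, and the controls of these lines at 0.907. The fit has 1 residual degree of freedom, to which the model adds 6.58 from the other genes. The p-values set the mean change of the 2 lines against a spread that comes mostly from other genes. They measure only in small part how alike the 2 lines responded, and genes whose lines stood apart could pass. Values after ± are limma's moderated SE, from that same spread, and not the spread between the 2 lines alone. Nothing in the labels says whether separate cultures were used. EGF in H322 has 1 array per condition and no test, so genes are counted at 2-fold when the higher signal is at or above the median of all probe sets, 7.28. The same rule with mean levels served the counts for erlotinib.

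The 22 gene lists, among them markers of leukocytes, of fibroblasts and endothelium, and of epithelial, mesenchymal and lung lineage cells, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list and with fry. In single lines each list's median was set against 10000 random lists of the same size drawn within 20 bins of mean level. Lists were fixed from textbook knowledge and not chosen on these samples. The genes named in the text follow a rule fixed beforehand: a short list of genes of EGFR signalling and inflammation, the 10 highest and 10 lowest past the threshold in both lines at or above the median level, the 10 highest and 10 lowest with EGF, the 5 highest and 5 lowest with erlotinib in each line, the 10 largest opposite changes, the 5 largest differences between control arrays in each direction, and up to 4 members of each list with the largest mean change. Where 1 or 2 members of a list passed outside this rule (KLF6, TGFA, IL6, VEGFA, TNFAIP2 and PDK1), they were named after their values were seen, as were ID1 and HCAR3. XIST and Y-linked genes are never named.

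The scripts were tested on simulated data with 17687 genes in 5 runs, with 200 genes changed. For the erlotinib comparison 25.8% of genes changed 2-fold and 95.6% of genes changed 4-fold were called, 9.67% of all calls were false, and at most 2 genes were called with no gene changed. For the lists 11 of 11 shifted lists and 0 of 11 others were called by camera. In 1 simulated pair 11 of the 11 shifted lists and 1 of the 11 others lay outside the percentile limits. The simulated noise was drawn independently for each gene, so it does not show how often lists of correlated genes are called falsely. The spread of each gene came from the fitted model with the trend, and both lines were given the same change. The share of false calls under another spread, or with lines that respond unlike, was not simulated.

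Alternatives fixed beforehand were no replicate block, quantile normalization, centring on medians, filters on level, the mean of probe sets, other models of the spread, all 6 arrays in 1 fit, the offset of 16 for the erlotinib test, other set tests, a 1.5-fold threshold and leaving out each line. Added after seeing the data were the offset of 16 for the other comparisons, dim signals raised to the 95th percentile of the negative controls, a filter to genes above that level on at least 1 of the 4 arrays, and centring and the mean of probe sets for the control arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.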

Results

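Gene expression was measured on 6 Clarion S arrays, 1 per cell line and condition, in 3 lung cancer cell lines. PC-9 and HCC827 are non-small cell lung cancer lines that carry a mutated EGFR, the epidermal growth factor receptor, and H322 is a lung cancer line with the wild-type receptor. Each EGFR-mutant line gave 1 control array and 1 array after 6 hours with 0.01 µM erlotinib, a small molecule that inhibits the EGFR kinase. H322 gave 1 control array and 1 array after 6 hours with its ligand EGF, at 100 µg/ml as the labels write it. The labels place the cells in medium with tumour necrosis factor alpha and leave open whether the control cultures received it too. If they did not, its effect cannot be told apart from that of erlotinib or EGF. The signals of 17687 named genes were used on the log2 scale. Between 48.8% and 52.4% of them lay above the 95th percentile of the negative control probe sets of their array. The number of arrays limits the precision: the 2 EGFR-mutant lines are the replicates of the erlotinib comparison, and the EGF comparison has none. Array and culture cannot be told apart within a line, so every value from a single line is without a replicate check.

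The first comparison asks what inhibition of EGFR does to gene expression in cells with a mutated receptor. The lowest values with erlotinib included those of genes known as outputs of ERK signalling. FOSL1, a subunit of the AP-1 transcription factor, fell by 5.13 ± 0.18 on the log2 scale (limma's moderated SE, n = 2 lines). The decrease was 35.0-fold, with an adjusted p of 9.2e-05 in limma. FOSL1 was lower by a similar amount in PC-9 (33.9-fold) and in HCC827 (36.1-fold). DUSP6, a phosphatase that inactivates ERK, fell by 4.21 ± 0.38 (limma adjusted p = 0.00861). It was at least 9.57-fold lower in PC-9, where the erlotinib array was not above the negative controls, and 9.91-fold lower in HCC827. The receptor tyrosine kinase EPHA2 fell by 2.96 ± 0.28, and CCND1, which encodes the G1 cyclin D1, fell by 2.11 ± 0.13, or 4.32-fold (limma adjusted p = 0.00875 and 0.0028). In total 262 genes passed the threshold of 0.05, of which 162 fell and 100 rose. All 262 had the same sign in both lines, but no gene of opposite signs could pass this test, so this is no separate sign of agreement.

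Further genes made up the lowest 10 past the threshold among genes at or above the median level. STC1, a secreted glycoprotein hormone, fell by 2.54 ± 0.20. PTX3, a pentraxin of innate immunity, fell by 2.50 ± 0.25, with the HCC827 erlotinib array below the negative controls. The adenosine receptor gene ADORA2B fell by 2.49 ± 0.30 and the semaphorin gene SEMA7A by 2.47 ± 0.22. NIPAL1, LONRF3 and PHLDA2 completed the lowest 10, with mean log2 changes of -2.81, -2.58 and -2.56. Limma adjusted p for these 7 genes lay between 0.00734 and 0.0182.

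The 10 highest increases past the threshold were taken among genes at or above the median level. Of these TNFSF10, which encodes the death ligand TRAIL, rose by 2.15 ± 0.24 on the log2 scale, or 4.45-fold (limma adjusted p = 0.0138). BMF, a BH3-only protein that promotes apoptosis, rose by 2.41 ± 0.33 (limma adjusted p = 0.0236). It was at least 3.20-fold higher in PC-9, whose control array was not above the negative controls, and 8.57-fold higher in HCC827. BCL2L11, another BH3-only gene, rose by 1.63 ± 0.21, or 3.09-fold (limma adjusted p = 0.0195). The epithelial transcription factor genes ELF3 and OVOL2 rose by 2.01 ± 0.27 and 1.98 ± 0.24. TCP11L2, YPEL3, TMEM140, KLHL24 and CXXC5 had mean log2 changes of 2.78, 2.77, 2.16, 2.10 and 2.03, with limma adjusted p between 0.0186 and 0.0442. The lines stood apart for TCP11L2, YPEL3 and KLHL24, with 1.59, 1.70 and 1.22 in PC-9 and 3.97, 3.83 and 2.98 in HCC827. The chemokine gene CXCL10 rose by 2.02 ± 0.24 (limma adjusted p = 0.0175), and was 3.28-fold higher in HCC827. In PC-9 neither CXCL10 signal lay above the negative controls, so no fold is given there.

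The count of genes past the threshold varied with the model of the spread and with other choices of processing. The design leaves 1 residual degree of freedom. Limma called 1 gene, FOSL1, with a spread that does not follow the level, and 0 genes with no block for the cell line, where 186 genes had an unadjusted p under 0.05 against 2540 with the block. It called 166 genes with an offset of 16, 96 among genes above the negative controls on at least 1 array, 636 with arrays centred on their medians, 954 after quantile normalization and 1115 with dim signals raised to the negative controls. Of 12 alternative fits HBEGF was called in 3, BCL2L1 in 4, KIF20A, KLHL24, PDK1 and TP53INP1 in 5 and F3, IL6, SLC2A1 and TCP11L2 in 6, and POLR1B in 3 of the 11 that tested it. In simulated data of this design 9.67% of the calls were false, more than the nominal share. That simulation took the fitted model of the spread as true, so it does not show the share if the model is wrong.

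At least 2-fold changes in the same direction in both lines were seen for 74 higher and 124 lower genes, where lists drawn independently in the lines would share 5.97 and 9.36. Of the 24 negative control probe sets at that level 3 also changed so, as did 30 of all 612, so some of these changes can be background. Of these 198 genes, 160 also passed the test. With dim signals raised to the negative controls, 157 genes changed at least 2-fold in the same direction in both lines. By log2 difference 3 genes changed at least 2-fold in opposite directions, SNAI2, ID1 and HCAR3, which were named after their values were seen. Neither HCC827 signal of SNAI2 and neither PC-9 signal of ID1 lay above the negative controls, and HCAR3, with 1 dim signal in each line, was at least 2.10-fold lower in PC-9 and at least 1.76-fold higher in HCC827. Among the genes named as past the threshold, 1 array of the pair was not above the negative controls for EPHA2, ADORA2B, PHLDA2, IL1B, HK2, OVOL2 and TMEM140 in PC-9 and for SEMA7A, PDCD1LG2, LIF, TRAF1, CXXC5, CLEC2B and TP53INP1 in HCC827, and both arrays for HBEGF in HCC827, so their log2 changes rest on 1 dim signal or more. The same holds for list members named below that did not pass: NR4A1, PFKFB3, CCNE1, CDC25A, CDT1, IFIT2, IDO1, IL1A, EREG, BCL2A1, SNAI1, LOX, SNAI2, SOX2, NKX2-1 and AQP5.

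**Figure D1:**
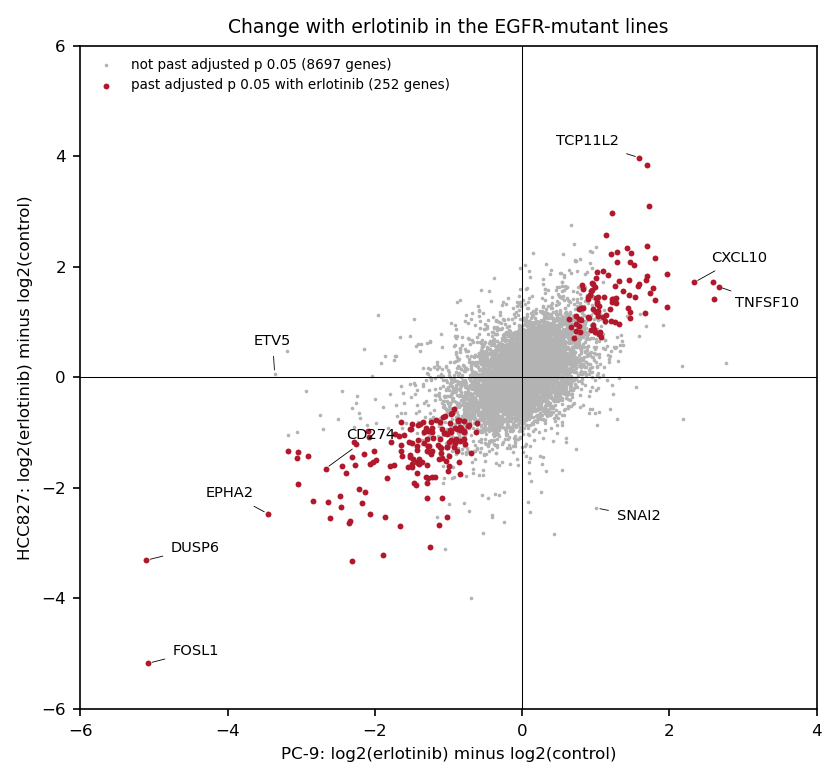
Log2 change with erlotinib in PC-9 (x axis) and HCC827 (y axis), log2 signal of the erlotinib array minus that of the control array, with 1 point per gene whose mean level was at or above the median, XIST and Y-linked genes left out. The 252 genes past the limma threshold (red) lie in the lower left and upper right quadrants, as the test requires. FOSL1 lies near -5 in both lines, and ETV5 is low in PC-9 alone.

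Gene lists fixed before the data were examined were tested against all other genes with camera, a set test of limma, at a preset correlation between genes, and 8 of 22 lists passed. None of the 8 passed with a correlation estimated for each list, which has 1 degree of freedom here: adjusted p was then 0.554 for 7 of them and 0.65 for the immune checkpoint list. The list of ERK feedback and output genes fell as a group, with a median log2 change of -1.59 and a camera adjusted p of 1.53e-22. Of its 20 measured members 8 fell past the threshold, 18 when adjusted over the list alone, and 12 did not pass over all genes. FOSL1, DUSP6 and EPHA2 were its lowest members. SPRY4, a feedback inhibitor of the pathway, had -2.28 ± 0.47, with the PC-9 erlotinib array below the negative controls, and did not pass (limma adjusted p = 0.0664). Nor did MYC, at -1.43 ± 0.35, or ETV4, at -0.82 ± 0.33 (limma adjusted p = 0.104 and 0.321). ETV5 had -3.36 in PC-9 and 0.06 in HCC827.

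Immediate early genes, which cells transcribe within minutes of a growth signal, fell as a list, with a median of -0.34 (camera adjusted p = 0.000326). The median was -0.18 with the offset of 16, -0.54 among genes over the median level and -0.17 with dim signals raised to the negative controls, a value that lists of dim genes take there too. Of 19 measured members 3 fell, 6 when adjusted over the list alone with 1 that rose, and 16 did not pass. The AP-1 gene JUN fell by 1.53 ± 0.27 (limma adjusted p = 0.0442). EGR1 fell by 1.78 ± 0.27 (limma adjusted p = 0.0326), with both PC-9 arrays below the negative controls and a 3.91-fold lower signal in HCC827. KLF6 fell by 0.98 ± 0.15 (limma adjusted p = 0.0326). CCN1 and NR4A1 had mean log2 changes of -1.23 and -1.21 and did not pass.

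Genes for making ribosomes formed the other list with a large decrease, with a median of -0.93 (camera adjusted p = 3.85e-18). Of 24 measured members 8 fell, 19 when adjusted over the list alone, 16 did not pass, and 21 were lower in both lines. DDX21, a nucleolar RNA helicase, fell by 1.74 ± 0.16, NOP16 by 1.48 ± 0.17 and LYAR by 1.52 ± 0.20 (limma adjusted p between 0.00875 and 0.0201). POLR1B, a subunit of RNA polymerase I, fell by 1.49 ± 0.27 (limma adjusted p = 0.049), with both PC-9 arrays and the HCC827 erlotinib array not above the negative controls. The glycolysis list fell with a median of -0.14 and a mean of -0.51 (camera adjusted p = 1.29e-05), and 4 of its 20 measured members fell, 8 when adjusted over the list alone. These included the glucose transporter genes SLC2A1 and SLC2A3, at -1.78 ± 0.30 and -1.73 ± 0.29, and the hexokinase gene HK2, at -2.19 ± 0.27. The SLC2A3 sequence is close to that of SLC2A14, so its signal is uncertain, and both HCC827 arrays were below the negative controls. PDK1 fell by 0.88 ± 0.15 (limma adjusted p = 0.0452), and PFKFB3 had -1.37 and did not pass.

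Genes that PI3K-AKT signalling holds down through FOXO factors rose as a list, with a median of 0.87 (camera adjusted p = 1.18e-11). With dim signals raised to the negative controls the median was 0.31, and 11 of the 21 members lay above the negative controls on all 4 arrays. Of 21 measured members 4 rose, 12 when adjusted over the list alone, and 17 did not pass. ERBB3, a receptor partner of EGFR, rose by 1.78 ± 0.16, or 3.43-fold, PIK3IP1, an inhibitor of PI3K, by 1.92 ± 0.20 and TXNIP by 1.61 ± 0.13 (limma adjusted p between 0.00734 and 0.0116). PDK4 rose by 2.71 ± 0.39 (limma adjusted p = 0.0269), with both PC-9 arrays and the HCC827 control below the negative controls. G2/M genes also rose as a list, by a median of 0.49 (camera adjusted p = 1.85e-10). Of 23 measured members 1 rose over all genes, KIF20A, a mitotic kinesin, at 0.92 ± 0.17 (limma adjusted p = 0.0482), 11 rose when adjusted over the list alone, and 20 were higher in both lines. CENPF, BUB1 and NEK2 had 0.90, 0.79 and 0.78 and did not pass. The list of G1/S and DNA replication genes had a median of -0.06 (camera adjusted p = 0.396), with 0 of 24 measured members past the threshold in limma, where 1 fell when adjusted over the list alone. CCNE1, CDC25A, CDT1 and CDC6 had -1.14, -0.87, 0.83 and -0.68.

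Interferon-stimulated genes rose as a list, with a median of 0.38 (camera adjusted p = 1.42e-08). Of 36 measured members 1 rose over all genes and 12 when adjusted over the list alone, 35 did not pass, and 27 were higher in both lines. The member that passed was GBP2, a guanylate-binding protein, at 1.42 ± 0.17 (limma adjusted p = 0.0175). IRF1, the transcription factor at the head of many interferon responses, had 0.88 ± 0.17, with 1.82-fold in PC-9 and 1.86-fold in HCC827, and did not pass (limma adjusted p = 0.053). IFIT2 and IRF9 had 1.15 and 0.90 and did not pass. With no block for the cell line this list, the immune checkpoint list and the glycolysis list no longer passed (camera adjusted p = 0.234, 0.234 and 0.0671).

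The immune checkpoint list fell with a median of -0.18 (camera adjusted p = 0.0159), and its medians were -0.40 in PC-9 and -0.01 in HCC827. Of its 20 measured members 2 fell, 4 when adjusted over the list alone. These were CD274, which encodes PD-L1, at -2.16 ± 0.26 (limma adjusted p = 0.0175), and PDCD1LG2, which encodes PD-L2, at -2.11 ± 0.23 (limma adjusted p = 0.0133). CD274 was at least 5.90-fold lower in PC-9 and 3.14-fold lower in HCC827. PVR and IDO1 had -1.11 and 0.96 and did not pass.

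**Figure D2:**
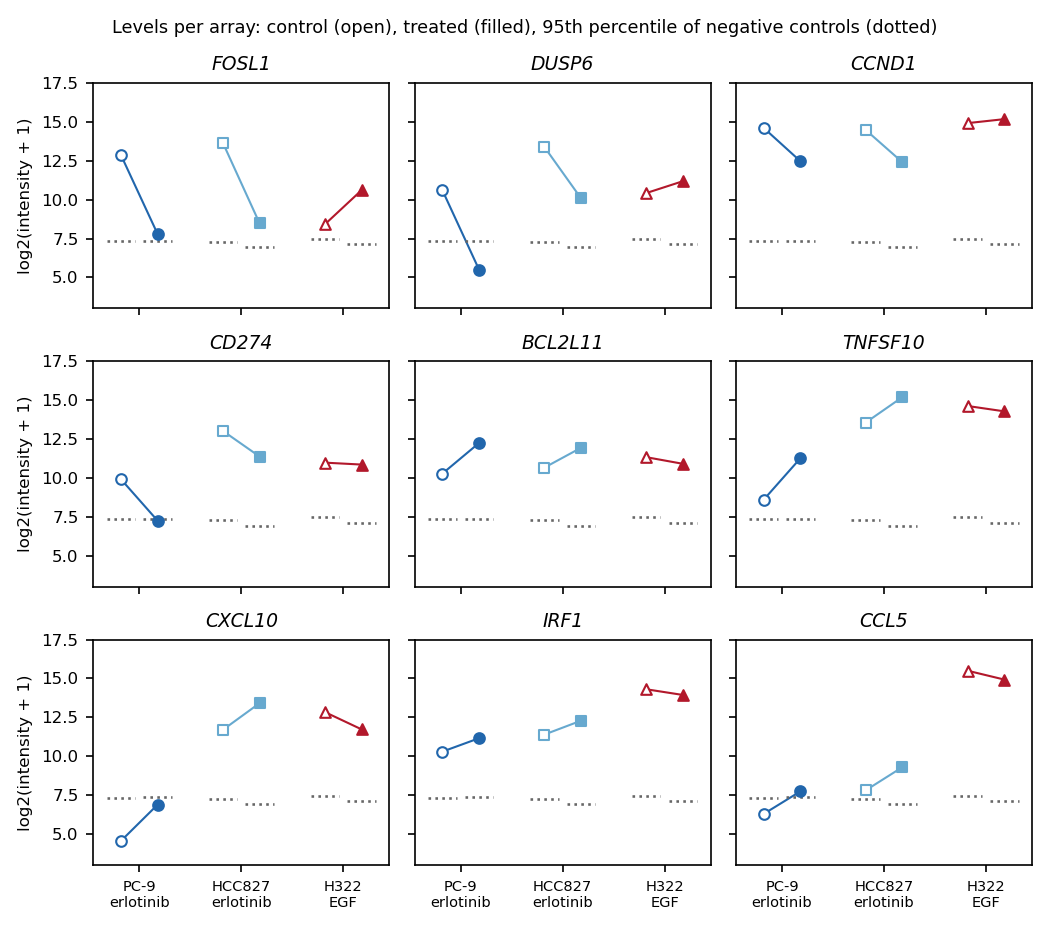
Level on each array, log2 of intensity + 1, of 9 genes in PC-9 (circles), HCC827 (squares) and H322 (triangles), with the control open and the treated array filled, and the 95th percentile of the negative controls of each array as a dotted line. FOSL1 and CCND1 are lower with erlotinib in both EGFR-mutant lines, BCL2L11 and TNFSF10 are higher, and in PC-9 both CXCL10 signals lie below the dotted lines.

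Chemokines and cytokines moved in both directions and the list did not pass (median -0.21, camera adjusted p = 0.115). Of 30 measured members 3 rose and 4 fell, with 4 and 6 when adjusted over the list alone. TNFSF10, CXCL10 and the T cell chemokine CCL5 rose, CCL5 by 1.47 ± 0.25 (limma adjusted p = 0.0424). It was at least 1.31-fold higher in PC-9 and 2.81-fold higher in HCC827. The cytokine genes IL1B and LIF fell by 2.45 ± 0.20 and 2.41 ± 0.24 (limma adjusted p = 0.00734 and 0.00973). IL6 and VEGFA fell by 1.28 ± 0.22 and 1.16 ± 0.14. CXCL8, which encodes interleukin 8, had -1.14 ± 0.23 and IL1A had -2.08 ± 0.44, and neither passed (limma adjusted p = 0.0607 and 0.0727). CCL22 was not above the negative controls on any of the 4 arrays. The NF-kappaB target list had a median of -0.08 (camera adjusted p = 0.765). In it TRAF1 and PTGS2 fell, at -1.82 ± 0.23 and -1.37 ± 0.17, TNFAIP2 rose by 0.70 ± 0.12, 18 of 21 measured members did not pass, and REL, CYLD and the inhibitor gene NFKBIA had 0.95, 0.86 and 0.49 without passing.

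The ERBB list did not pass (median -0.23, camera adjusted p = 0.0635), while its feedback inhibitor ERRFI1 fell by 1.76 ± 0.17 and the ligand gene HBEGF by 2.19 ± 0.40 (limma adjusted p = 0.00973 and 0.0489). EREG had -1.57 without passing, and EGFR itself had -0.23 ± 0.16 (limma adjusted p = 0.575). TGFA, another ligand gene, fell by 1.56 ± 0.25 (limma adjusted p = 0.0377). Of the 12 measured members of the list 1 rose, ERBB3, 3 fell and 8 did not pass. In the BCL2 family BMF and BCL2L11 rose and BCL2L1, which encodes the survival protein BCL-xL, fell by 1.23 ± 0.22 (limma adjusted p = 0.0482). BCL2A1 had -0.86, 11 of 14 measured members did not pass, and the list had a median of -0.15, a mean of 0.10 and a downward camera direction (adjusted p = 0.926). Among 16 measured p53 targets TP53INP1 rose by 1.86 ± 0.33, CDKN1A, an inhibitor of cyclin-dependent kinases, fell by 1.48 ± 0.19 and AEN, a nuclease, fell by 2.31 ± 0.20. XPC had 0.82 and did not pass. The median of that list was 0.05, its mean -0.07 and its camera direction down (adjusted p = 0.922).

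Antigen presentation through MHC class I did not pass (median 0.13, camera adjusted p = 0.0516, 0 of 17 measured members in limma, over all genes or over the list alone). PSMB10, HLA-E, HLA-G and HLA-C had 0.65, 0.55, 0.42 and 0.40, the HLA genes being close in sequence and so uncertain, and B2M had 0.12. The cholesterol synthesis list had a median of -0.14 (camera adjusted p = 0.0536) with none of 18 measured members past the threshold, and SQLE, HMGCS1, STARD4 and CYP51A1 had -0.63, -0.54, -0.50 and -0.34. In the ATF4 list, with a median of 0.00, a mean of -0.22 and a camera adjusted p of 0.132, STC2 and TRIB3 fell by 2.06 ± 0.19 and 1.27 ± 0.21, NUPR1 rose by 1.29 ± 0.21, DDIT4 had -1.32 without passing, and 17 of 20 measured members did not pass. Epithelial genes had a median of 0.17 (camera adjusted p = 0.219), with ELF3 past the threshold and CLDN3, GRHL2 and OCLN at 0.73, 0.54 and 0.37. Mesenchymal genes had a median of -0.02 (camera adjusted p = 0.337), and SNAI1, LOX, SNAI2 and ITGA5 had -1.17, -0.80, -0.68 and -0.66 without passing. Lung lineage genes had a median of 0.08 (camera adjusted p = 0.396), and 2 of 18 members lay above the negative controls on all 4 arrays. SOX2 and NKX2-1, dim on both PC-9 arrays, had 1.71 and 0.72, AQP5, dim on all 4, had -0.38, and FOXA1 had 0.64, without passing. Markers of leukocytes and of fibroblasts and endothelium had medians of 0.01 and 0.03 (camera adjusted p = 0.939 and 0.926), and 2 of 19 and 1 of 16 members lay above the negative controls on all 4 arrays.

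**Figure D3:**
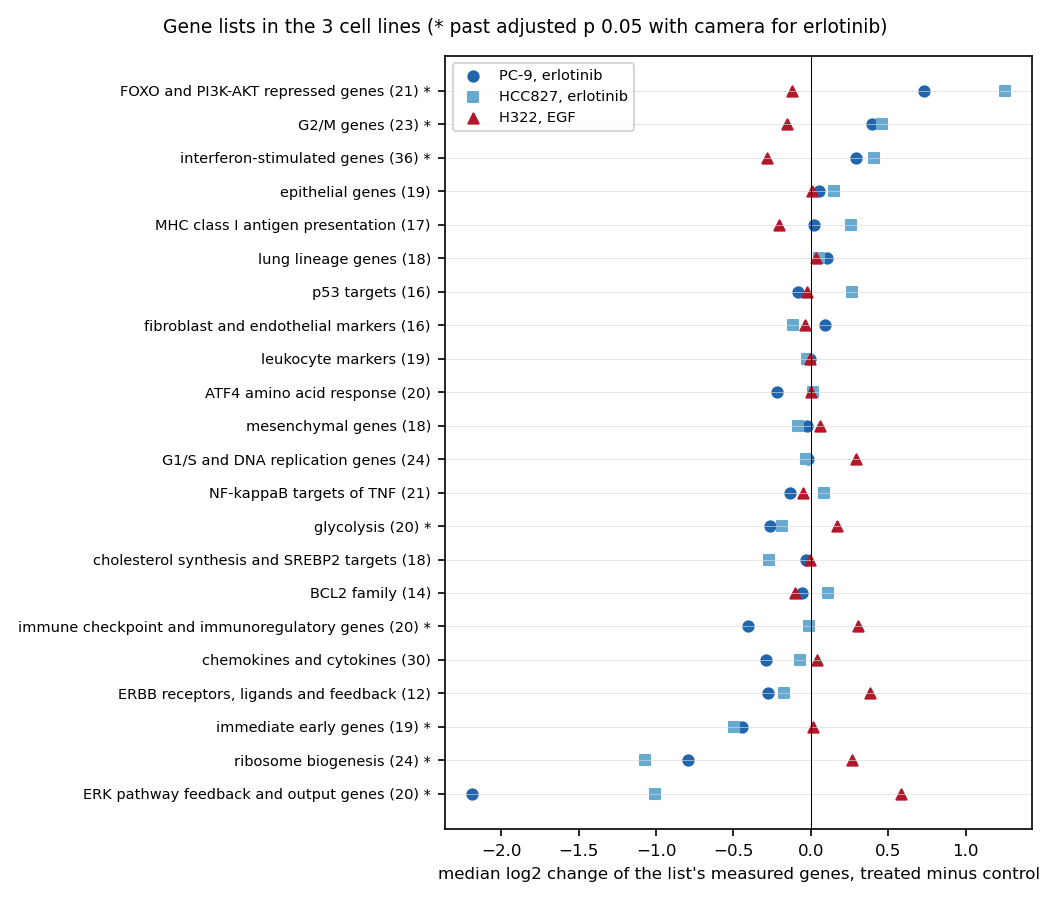
Median log2 change, treated minus control, of each of the 22 gene lists in PC-9 with erlotinib (circles), HCC827 with erlotinib (squares) and H322 with EGF (triangles), with the number of measured genes after each name and an asterisk for the 8 lists past the camera threshold with erlotinib. The ERK list lies at -2.19, -1.01 and 0.59, and the interferon-stimulated list at 0.29, 0.41 and -0.28.

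Set side by side, the EGFR-mutant lines changed in the same direction for most genes. Among 900 genes at least 2-fold changed in either line, 770 (85.6%) had the same sign in both, against 67.2% of all genes at the same level. Pearson's r across genes was 0.557 and Spearman's rho 0.498, where genes are not independent replicates. Without the level filter r was 0.38 and the share 77.7%. At least 2-fold, 164 genes were higher and 314 lower in PC-9, and 454 were higher and 340 lower in HCC827. By log2 difference, in which dim signals weigh in, the highest in PC-9 were SLC7A7, TNFSF10, HEG1, ELF3 and TMEM140, and the lowest were DUSP6, FOSL1, NOG, ACP7 and EPHA2. The control signals of SLC7A7 and TMEM140 were not above the negative controls, and these genes were at least 1.63-fold and 1.35-fold higher, against 6.35-fold for TNFSF10. DUSP6 and EPHA2 were at least 9.57-fold and 8.05-fold lower, against 33.9-fold for FOSL1. NOG and ACP7 were at least 8.19-fold and 8.94-fold lower in PC-9 and not above the negative controls in HCC827. The highest in HCC827 were SNPH, TCP11L2, YPEL3, PDK4 and STAU2-AS1, and the lowest were FOSL1, DKK1, NIPAL1, DUSP6 and PHLDA2. SNPH was at least 7.47-fold higher in HCC827 and not above the negative controls in PC-9, and the HCC827 control signals of PDK4 and STAU2-AS1 were not above the negative controls either. DKK1 was at least 2.62-fold lower in HCC827 and 1.62-fold lower in PC-9. With 1 pair per line, no difference between the lines was tested.

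The next comparison asks what stimulation of the wild-type receptor does. Changes were smaller in H322 with EGF: 18 genes were at least 2-fold higher and 15 lower, and the SD of the log2 differences over genes at or above the median level was 0.27, against 0.49 in PC-9 and 0.57 in HCC827. FOSL1 was the highest, at 2.20 on the log2 scale, or 4.59-fold. By log2 difference WNT7A, a secreted signalling protein, came next, but its control signal lay below the negative controls and its bound was at least 2.40-fold. The matrix protease gene MMP7 was 2.48-fold higher, CLEC2B 2.31-fold, NEK6 2.17-fold and the integrin gene ITGA2 2.16-fold. NOL4L, ZIC5, MAGEH1 and RASAL3 were among the highest 10, but their control signals were not above the negative controls and the bounds were at least 1.20-fold, 1.57-fold, 1.02-fold and 1.15-fold. Among the lowest were BATF (2.34-fold lower), PGLYRP2 (2.33-fold), NOS2 (2.29-fold), RNPC3 (2.23-fold), CXCL10 (2.16-fold) and CEACAM19 (2.08-fold). MIR99AHG, KCNJ2, PDGFRL and TMEM131L completed the lowest 10, with EGF signals not above the negative controls and bounds of at least 1.35-fold, 1.55-fold, 1.29-fold and 1.96-fold. CCL22, a chemokine for regulatory T cells, was 1.97-fold higher and IRF1 1.29-fold lower. There is no test for these values, and the counts were 70 and 63 without the level filter and 3 and 2 at a level over the 75th percentile.

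Lists were set against 10000 random lists matched on level, as a description of these arrays. With EGF, 10 of 22 lists had a median outside the central 95%. The ERK list (median 0.59), the G1/S list (0.29), the ERBB list (0.38), the ribosome biogenesis list (0.27) and the immune checkpoint list (0.30) lay above every random list, and glycolysis (0.17) above 99.97% of them. The interferon-stimulated list (-0.28) lay below every random list, and the MHC class I list (-0.20), the G2/M list (-0.15) and the FOXO list (-0.12) lay at percentiles of 0.01, 0.03 and 1.69. With erlotinib, 11 lists in PC-9 and 9 in HCC827 lay outside. The ERK, immediate early, ribosome biogenesis and glycolysis lists were low and the G2/M, interferon-stimulated and FOXO lists high in both lines. Lists low in PC-9 and inside the limits in HCC827 were ERBB, chemokines and cytokines, immune checkpoint and ATF4. In HCC827 cholesterol synthesis was low and MHC class I high, and both lay inside the limits in PC-9. These differences between lines were not tested.

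The responses to erlotinib in the mutant lines and to EGF in H322 ran in opposite directions for most genes that changed. Of 202 genes at least 2-fold lower in the mean of the EGFR-mutant lines, 180 (89.1%) were higher with EGF, with a median EGF change of 0.38. Of 150 genes at least 2-fold higher, 124 (82.7%) were lower with EGF, with a median of -0.24. Of all 8291 genes at that level, 51.5% were higher with EGF. Across them Pearson's r was -0.415 and Spearman's rho -0.373, with r of -0.336 for PC-9 alone and -0.399 for HCC827 alone. The pairs share no control array. The share of opposite genes, 86.4% of 352, was 81.7% without PC-9 and 79.9% without HCC827.

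By log2 differences of at least 1 in both comparisons, 9 genes were lower with erlotinib and higher with EGF, where independent lists would share 0.39, and CXCL10 and PDGFRL were higher with erlotinib and lower with EGF, where independent lists would share 0.163. Dim signals enter these counts: PDGFRL was at least 1.29-fold lower with EGF, WDR4 at least 1.62-fold higher, and CXCL10 had no signal above the negative controls in PC-9, nor had SLC2A3 and WNT7A in HCC827. MMP7 and CLEC2B were higher in both comparisons, CLEC2B at least 1.20-fold in HCC827 with a dim control, and 0 genes were lower in both. By log2 differences, the largest opposite changes were those of FOSL1, CXCL10, ITGA2, AEN, SLC2A3, WDR4, SLC19A1, NIPAL1, F3 and RCL1. For CXCL10 and SLC2A3 they rest on 1 EGFR-mutant line and H322. The H322 control signals of SLC2A3, WDR4 and RCL1 were not above the negative controls, nor were the PC-9 erlotinib signals of WDR4 and RCL1. ITGA2 had -1.36 with erlotinib and 1.11 with EGF, AEN -2.31 and 1.09, the folate carrier gene SLC19A1 -1.48 and 0.98, and F3, which encodes tissue factor, -2.15 and 0.96. WDR4 and RCL1, at -1.16 and -1.28, did not pass the erlotinib test. Of the interferon-stimulated genes 29 of 36 and of the G2/M genes 19 of 23 were lower with EGF, and 22 of 24 ribosome biogenesis genes and 19 of 20 ERK genes were higher.

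**Figure D4:**
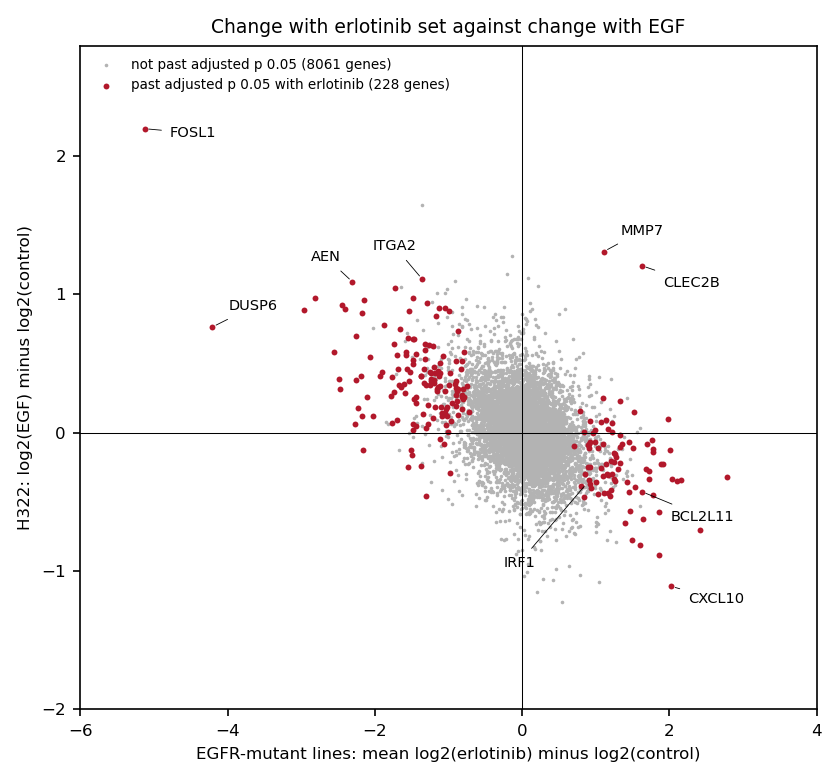
Mean log2 change with erlotinib in PC-9 and HCC827 (x axis) against the log2 change with EGF in H322 (y axis), with 1 point per gene at or above the median level, XIST and Y-linked genes left out. Most of the 228 genes past the limma threshold for erlotinib (red) lie in the upper left and lower right quadrants, with FOSL1 at -5.13 and 2.20 and with MMP7 and CLEC2B higher in both.

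The last comparison sets the control arrays of the lines beside each other. With 1 array per line and 1 wild-type line, genotype and line cannot be separated. By log2 difference, 377 genes were at least 4-fold higher and 305 at least 4-fold lower in H322 than in both EGFR-mutant lines. With dim signals raised to the negative controls these counts were 268 and 203. By a looser rule, a difference in either direction between 2 lines, 1598 genes differed at least 4-fold between PC-9 and HCC827. No such count was made against H322. Across genes the control arrays correlated at 0.907 for PC-9 and HCC827, 0.907 for PC-9 and H322 and 0.910 for HCC827 and H322. CCL5 was 207-fold higher in H322 than in the higher of the EGFR-mutant lines. S100A8, a calcium-binding protein of inflamed epithelium, was at least 129-fold higher, PSTPIP2 at least 58.5-fold, and the proton pump genes ATP6V1C2 and ATP6V1B1 at least 111-fold and 99.8-fold. The cell cycle inhibitor gene CDKN2A was at least 165-fold lower in H322, the glutathione transferase gene GSTP1 at least 237-fold, TNFRSF9 at least 111-fold, TXNIP at least 33.7-fold and ARSD at least 20.7-fold, all with H322 signals below the negative controls. FOSL1 was 22.0-fold lower in H322 than in PC-9 and IRF1 was 7.54-fold higher in H322 than in HCC827. The EGFR signal in HCC827 was 6.04-fold that in PC-9 and 12.6-fold that in H322.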

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

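The tests of ETV5 given here were chosen after its values were seen, and no difference between the lines was tested, since each line has 1 control and 1 erlotinib array. Genes are given because their log2 change with erlotinib had opposite signs in PC-9 and HCC827, and differed by at least 1. The change in PC-9 minus that in HCC827 was -3.42 for ETV5, 1.21 for BATF, 2.91 for HEG1, -5.47 for SNPH, 1.59 for PSTPIP2, 3.36 for SNAI2, -1.36 for FOXA1, -2.51 for HCAR3 and -3.09 for ID1. Several of these rest on dim signals: BATF, HEG1, SNAI2 and PSTPIP2 were not above the negative controls on either HCC827 array, and SNPH, PSTPIP2 and ID1 on either PC-9 array. HCAR3 was not above them on the PC-9 erlotinib and HCC827 control arrays, nor SNPH on the HCC827 control array, so ETV5 and FOXA1 alone had 4 signals above background. Lists are given because their medians had opposite signs in the lines. The difference of medians was -0.22 for NF-kappaB targets, -0.17 for the BCL2 family, -0.35 for p53 targets, -0.23 for the ATF4 list and 0.21 for fibroblast and endothelial markers, and in none of these did the list pass the camera test.

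ETV5, a transcription factor gene that ERK signalling induces, had -3.36 with erlotinib in PC-9 and 0.06 in HCC827, with control levels of 12.5 and 9.54. A signal near background in HCC827 is argued against by its level, since on both HCC827 arrays it lay at least 2.26 log2 units above the 95th percentile of the negative controls. For a weaker response of HCC827 as a whole, the SD of its changes over genes was 1.16 times that of PC-9. This cannot decide the question, since the negative control probe sets, which have no target gene, also spread more in HCC827. Their SD was 1.06 in HCC827 and 0.946 in PC-9. A weaker response of ERK output alone in HCC827 stays open, with medians of the ERK list of -2.19 in PC-9 and -1.01 in HCC827 and MYC at -2.31 and -0.56, while FOSL1 had -5.08 and -5.17. A difference between the lines in how ETV5 is regulated, or a fault of 1 array, stays open as well, and none of these was tested.

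Probe sets that carry no gene symbol are not part of the comparisons. Of 1042 such probe sets at or above the median level, 17 changed at least 2-fold in the same direction in both EGFR-mutant lines, 4 of them higher and 13 lower. Of 24 negative control probe sets at that level 3 did so, as did 30 of all 612, so changes of this size also arise without a target gene.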

How the results depend on the processing

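Among alternatives added after seeing the data are the flooring of dim signals, the filter on negative controls, and the offset of 16 outside the erlotinib test. The counts for erlotinib (262 genes, 100 higher and 162 lower) moved most. They were 0, 0 and 0 with no replicate block (186 genes at unadjusted p under 0.05 in limma, lowest adjusted p 1) and 1, 0 and 1 without the trend (2255 unadjusted). They were 636, 270 and 366 with centred arrays, 954, 449 and 505 after quantile normalization, 1115, 533 and 582 with floored signals, and 96, 27 and 69 among genes above the negative controls. With the offset of 16 they were 166 genes and 58 higher, and over the 25th percentile of level 63 were higher. The 262 genes were all among those called after centring and after quantile normalization. The prior degrees of freedom behind these counts went from 6.58 to 9.97 with centring and to 18.4 after quantile normalization, and fell to 4.46 without the trend. Flooring gives dim genes the same change within a line, so its count is no stronger evidence. A robust spread, all 6 arrays in 1 fit, the filter at the median level and the mean of probe sets stayed within 1.5 times of 262.

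Of 72 calls for named genes or list members 52 were kept with the offset of 16, 58 over the 25th percentile and 43 among genes above the negative controls, and none turned. With flooring the changes of PDK4, POLR1B, CXCL10, EGR1, TMEM140, IL1B and CCL5 were 0.30, -0.60, 0.86, -0.98, 1.08, -1.37 and 0.94, and that of CLEC2B was smaller by over 1.5 times as well.

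With a line left out no test remains. Of 164 gene changes 97 then moved by more than limma's moderated spread for the gene. For genes this count must be the same whichever line is left out, since the mean of 2 lines moves equally far either way. Of 22 list medians 9 moved by more than their spread in each case. JUN, HBEGF and BCL2L1 had -0.97, -1.35 and -0.82 in HCC827 alone, and F3, TP53INP1 and SLC2A1 -1.25, 1.14 and -1.03 in PC-9 alone. The genes at least 2-fold higher in the mean (176) were then 145 to 404, those lower (234) 283 to 302, and the opposite share 79.9% to 81.7%. Lists called (8) were 5 with no replicate block, 13 after quantile normalization, 13 with floored signals, 0 with an estimated correlation and 0 with fry (lowest adjusted p 0.256). The ATF4 list, with a median near 0, turned to -0.0286 after quantile normalization and to -0.0245 with flooring, and passed there. With flooring 7 lists lay outside the limits in PC-9 in place of 11.

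The EGF counts (18 and 15) were 197 and 159 at 1.5-fold, 3 and 2 over the 75th percentile, 70 and 63 with no level filter, and 11 and 9 with flooring. Flooring also turned the EGF change of MAGEH1 to -0.0351, of CD68 to -0.0306, and of DKK1 and TNFRSF9 to -0.34, the last being the distance between the floors of the H322 arrays. The same-sign share of PC-9 and HCC827 (85.6%) was 80.1% at 1.5-fold, 94.9% over the 75th percentile and 77.7% with no level filter, where r was 0.38. The opposite share (86.4%) was 78.8%, 90.6% and 79.2% under these, with r of -0.223 under the last, and 78.4% with flooring. Genes at least 4-fold lower in H322 (305) were 203 with flooring. Flooring moved the median change of all genes to -0.35 in HCC827 and -0.34 in H322, and centring to -0.07 in HCC827. Apart from the changes given with flooring, the causes were not tested. Signal over background limits all of this, since 48.8% to 52.4% of genes lie above the negative controls.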

Other observations

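The tests of scaling, of single members and of ERK output reported here were chosen after the results were seen, while those of a trend with level and of the negative controls were written once the correlation over genes was known and before their own outcome was. Families of genes that share a symbol root were screened as well, also after the data had been seen. Of 88 families with at least 10 measured members 9 passed camera at the preset correlation, and none with an estimated correlation (adjusted p = 0.935 for each). The UTP family of ribosome assembly factors had a median of -0.62 with erlotinib (camera adjusted p = 0.000142), with 10 of 10 members lower in both lines and 10 of 10 higher with EGF. Mitochondrial import genes of the TIMM family had -0.33 (camera adjusted p = 0.00633) and DDX helicases -0.19 (camera adjusted p = 0.0336). The IFT family of intraflagellar transport genes had 0.38 (camera adjusted p = 0.0249), with 10 of 14 members higher in both lines and 0 lower in both. TRIM and KIF genes had 0.29 and 0.17, and EIF, SLC and DUSP genes -0.12, -0.12 and -0.39.

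Erlotinib and EGF changes ran in opposite directions across genes, with r of -0.415. A trend of the change with the level within each pair is argued against, since r was -0.415 once a loess trend was removed. Over the 612 negative control probe sets r was -0.0615, with a 95% interval from -0.14 to 0.0178. The interval excludes -0.415 for noise of the kind these probe sets carry. Only 24 of them lay at or above the median level in the EGFR-mutant lines, while the -0.415 comes from genes at that level. Noise shared by brighter signals therefore cannot be excluded by this test. A smaller part from noise of the dim kind stays open too, since the interval does not clear the bound of -0.1 set beforehand. Opposite changes in ERK signalling are a candidate explanation, and the ERK list lay above 100% of the random lists with EGF while it was the lowest list with erlotinib. The immediate early list, which also fell with erlotinib, had a median of 0.02 with EGF (percentile 56.1), with 10 members higher and 9 lower. As 1 line received EGF and other lines erlotinib, line and treatment cannot be separated here.

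Interferon-stimulated and G2/M genes were higher with erlotinib and lower with EGF. A shift from scaling all arrays to one median stays open: the smaller excess of a list over level-matched random lists was 0.339, but the scaling itself holds such lists near 0. At least 75% of the members of each list were higher in both lines, so the rise was spread over most members. This is no separate test of a few members carrying the lists. The pattern was picked with both medians above every random list in both lines, and a few members cannot move a median so far. The lung lineage list, also with medians above 0 in both lines but inside the limits, had 5 of 18 members higher in both. Whether tumour necrosis factor alpha in the medium plays a part was not tested, since no array is labelled as without it. The labels leave open whether the control cultures received it. If they did not, its effect cannot be told apart from that of erlotinib or EGF. The lists' calls were lost with an estimated correlation.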
